A study of Canis lupus familiaris with 8 samples.

How the data were processed

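The study measured gene expression in frozen sections of dog cephalic vein with Visium, an array of barcoded capture spots that reads out the RNA of the tissue lying over each spot. Each of the 8 libraries is 1 section. There were 4 libraries of undistended control vein, from dogs 1 to 4, 3 libraries of vein after pressure distension, from dogs 2, 3 and 4, and 1 library of vein graft, from dog 1, taken 24 h after carotid bypass. The grafted vein had also been distended before it was implanted, per the labels, so graft against control includes distension, and graft against distended vein does not separate time in the circulation from the dog. Per the labels, the animals were mongrel dogs of 25 kg, 3 male and 1 female (dog 4). The vein was distended with a saline solution that held papaverine and bivalirudin, over a harvest of about 30 min, and the tissue was permeabilised for 9 min.

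The deposited values are counts of unique molecular identifiers (UMIs) per gene and spot, with no normalization. Space Ranger 2.0.0 made them, per the submitters' processing notes and the file headers. The genome build, the annotation and the way spots were kept are not given in the sources used here. Spot positions and the stained images were not used here, so regions were defined from expression alone. The files held 35555 feature names, of which 34403 ended in a numeric suffix. Names that differed only by suffix were summed, which gave 35120 genes, 89 of them merged from several features. A RefSeq gene table of the dog assembly UU_Cfam_GSD_1.0 held 33471 of these names. The table was used only for names and neighbouring genes, and no coordinates are given because the files name no build. The 17349 genes known only by a LOC identifier were treated as having no symbol. A further 24 features that name no gene held 0.20% to 0.944% of the UMIs of a library and were left out of library sizes and tests. All 13 mitochondrially encoded features stood at 0 UMIs in all 8 libraries, so the planned check of the mitochondrial share could not be made.

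The libraries held 4903 spots and 7858250 UMIs in named genes. The deepest was the grafted vein (2526568 UMIs, 968 spots) and the shallowest the distended vein of dog 4 (172592 UMIs, 493 spots). A count of 0 in a library allowed up to 1.19 CPM (counts scaled to a common library total) in the deepest library and 17.4 CPM in the shallowest, taking 3 counts as the limit. Intervals and limits of this kind cover counting error only. No 2 libraries agreed within sampling noise, since chi-square over degrees of freedom was at least 3.75 for each of the library pairs.

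Spots are not replicates, so counts were summed over all spots of a library and tested across libraries. The test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr by group and robust estimation, fitted to all 8 libraries with a coefficient per group. It tested 10261 genes, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are log2 values with a standard error (SE) equal to the size of the log2 fold change over the square root of F. The fit had 5 residual degrees of freedom, which come from the control and distended libraries. The single grafted library was assumed to vary like the other groups and has no replicate check. Where the lower group stood at 0, the text gives a lower bound, the mean CPM of the higher group over 3 counts in the whole lower group. Where it held 1 to 3 counts, the text gives the 95% exact counting interval of the ratio. A fitted log2 fold change of such a gene depends on a prior count and is not given.

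Libraries with the same number come from the same dog, per the labels, so the numbers pair the samples. As a check, deviations from the group mean correlated between the control and distended libraries of the same dog at -0.025 for dog 2, 0.132 for dog 3 and 0.082 for dog 4. Pairs of different dogs correlated at -0.130 to 0.058, so dogs 3 and 4 lay above that range and dog 2 within it. The design fixed before the data were examined has no term for the dog. A fit with the dog as a block, which has 2 residual degrees of freedom, is given beside a result where it changed the call or moved a count by over 1.5 times. In this fit the grafted vein is compared with the control vein of dog 1 alone.

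Gene lists were fixed before the data were examined. The 13 lists of cell type markers were smooth muscle, fibroblast, endothelial, pericyte, macrophage and monocyte, neutrophil, lymphocyte, mast cell, adipocyte, skeletal muscle, Schwann cell and nerve, red cell, and platelet. The lists of processes were immediate early genes, heat shock and chaperones, inflammatory cytokines and adhesion, YAP and TEAD targets, matrix remodelling, collagen and elastic fibre, coagulation and fibrinolysis at the vessel wall, hypoxia and glycolysis, unfolded protein and integrated stress, mitochondrially encoded genes, nuclear oxidative phosphorylation, cell cycle, interferon response, phagocyte activation and lipid handling, and cytosolic ribosomal proteins. The 23 lists with at least 5 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2, and again with an estimated correlation and with fry. Marker levels per library are the summed UMIs of a list per 10000 UMIs. Distended and control levels were compared on log2(level + 0.1) with a two-sided exact permutation test over all 35 splits, whose smallest possible p is 0.0286.

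The named genes follow a rule written before the data were examined. For the distended and the grafted vein against control, these are up to 12 genes in each direction with the largest change among genes with a symbol, past the threshold, with 10 or more CPM in the higher group and the same direction in each pair of a dog. The grafted vein also had to differ in that direction from each of the 4 controls. Where fewer than 5 passed, the genes of lowest p fill up to 5 and are said not to have passed. For each described list up to 4 members are named (some named by this rule are not reported here), for the grafted vein against the distended veins 5 in each direction, and for each region its 5 leading genes. The choice to describe the lists called with or without the dog as a block was made after the list results were seen.

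Regions of spots were found with scanpy 1.11.5 and igraph 0.11.9. The 561 spots under 200 UMIs were left out. The other 4342 spots were scaled to 10000 UMIs, log transformed, reduced to 2000 variable genes scaled within each section and 30 principal components, and clustered with the Leiden algorithm on 15 neighbours at resolution 0.5. Leading genes were ranked by the log2 ratio of CPM + 10 inside and outside the region, averaged over sections with 20 or more spots. A region was tested where 3 or more control and 2 or more distended libraries had 20 or more spots. A spot holds several cells, so a region is described by its leading genes and is not a cell type. The muscle region and the fibroblast region are those with the highest mean level of the smooth muscle and the fibroblast list. Shares of spots are described and not tested, because scaling within a section and the changed genes themselves can move them.

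The edgeR steps were tested on simulated counts for the 10261 genes, with 200 genes changed by a known fold. For distended against control, 2.5% of the changed genes were recovered at 2-fold, 69.5% at 4-fold and 84.5% at 8-fold, with at most 11 false calls. For grafted against control, 0% were recovered at 2-fold, 34.5% at 4-fold and 77.5% at 8-fold, with at most 19 false calls. Alternatives fixed before the data were examined covered DESeq2 1.42.0, limma-voom, upper quartile and total count scaling, other filters, spots of 500 or more UMIs, thinning to the smallest library, equal weight for each spot, the dog as a block, male dogs only and leaving out each library. Alternatives added after the data were seen are named where they are used. For the planned thinning the tool was replaced after its result was seen. The edgeR function for thinning, run first, kept a correlation with full-depth fold changes of 0.584, and sampling without replacement, which kept 0.935, took its place, with both results given. Over 10 further draws, made after both results were seen, sampling gave 732 to 810 calls for grafted against control and the edgeR function 368 to 464. Exact tests used scipy 1.17.1 and pandas 2.3.3.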

Results

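Gene expression was measured with Visium in sections of dog cephalic vein, the forelimb vein used here as a bypass conduit. There were 4 control veins (dogs 1, 2, 3 and 4), 3 veins after distension during harvest (dogs 2, 3 and 4) and 1 vein graft 24 h after carotid bypass (dog 1), which per the labels had been distended at harvest as well. The control libraries held 1819303, 615304, 387376 and 274021 UMIs in named genes for dogs 1 to 4, over 798, 393, 305 and 305 spots. The distended libraries of dogs 2, 3 and 4 held 907528, 1155558 and 172592 UMIs over 916, 725 and 493 spots, and the grafted library held 2526568 UMIs over 968 spots. The median UMI count per spot was 1156 ± 551 (SD, n = 4) in control and 598 ± 357 (SD, n = 3) in distended veins, and 2191 in the graft. Distended minus control was -558 (exact permutation p = 0.257), which with so few libraries does not show equal depth. The share of ribosomal protein counts was 9.00% ± 1.57 (SD, n = 4) in control and 9.73% ± 2.40 (SD, n = 3) in distended veins (exact permutation p = 0.571), and without the distended vein of dog 4 the sign of that difference turned.

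The first question was which cell type markers each vein carried. Smooth muscle markers were the most abundant of the lists in control veins, at 611 ± 190 (SD, n = 4) UMIs per 10000, followed by fibroblast markers at 209 ± 136 and endothelial markers at 23.1 ± 7.70. In the graft, neutrophil markers stood at 90.4 UMIs per 10000, 29.5-fold the control mean of 3.07 ± 0.949, and macrophage and monocyte markers at 31.4, 6.86-fold the control mean of 4.58 ± 2.78. Smooth muscle markers stood at 82.5 in the graft, 7.41-fold below the control mean and below each of the 4 controls. Fibroblast (65.9), pericyte (2.88), skeletal muscle (2.47), Schwann cell and nerve (0.210) and adipocyte (2.11) markers were also below the lowest control, while endothelial markers (27.3) lay within the control range. Against the control of dog 1 alone, macrophage and monocyte markers were 3.65-fold higher and neutrophil markers 42.1-fold, and smooth muscle markers stood at 0.206, fibroblast markers at 0.171 and adipocyte markers at 0.123 of its level (0.135, 0.315 and 0.311 of the control mean).

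Other lists lay within the control range or near it in the graft. Lymphocyte markers stood at 0.653 against 0.528 ± 0.0681 in control veins, just above the highest control of 0.585. Mast cell (0.368), red cell (0.0356) and platelet (0.313) markers lay within the control range, and stood at 0.598, 0.24 and 0.360 of control 1. Of the red cell list only 5 of 9 members were in the files and 1 was tested. Its level therefore says little about blood in the graft. The graft is a single library, so these levels were set against the control range and not tested.

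**Figure D1:**
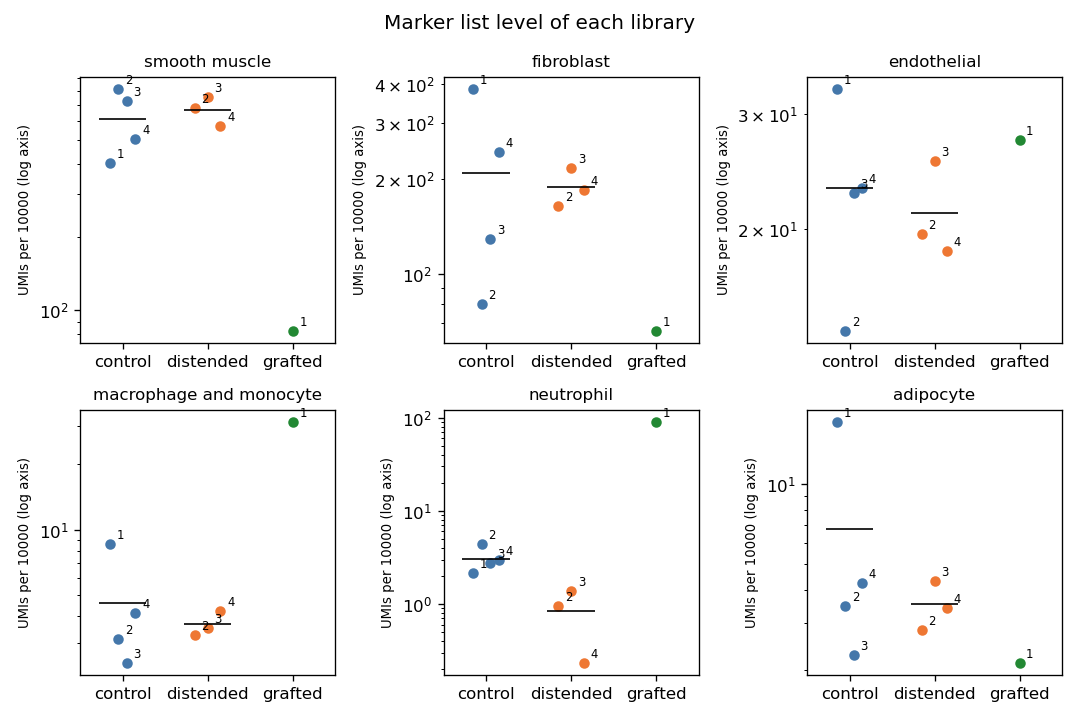
Summed marker UMIs per 10000 UMIs of each library (log axis, a different range in each panel) for 6 cell type lists, with 1 point per library, the dog's number beside it and a line at the mean of groups with more than 1 library. The graft of dog 1 lies at 90.4 for neutrophil markers, above all 4 controls, and at 82.5 for smooth muscle markers, below all 4 controls.

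Distended veins were compared with control veins to ask what distension during harvest, over about 30 min, did to the transcriptome. Neutrophil markers were lower in all 3 distended veins than in any control vein. Their level was 0.852 ± 0.578 (SD, n = 3) UMIs per 10000 against 3.07 ± 0.949 (SD, n = 4), a log2 difference of -1.94 (exact permutation p = 0.0286, the smallest this design can give, and 0.371 after Benjamini-Hochberg adjustment over 13 lists). Within dogs 2, 3 and 4 the level was lower in 3 of 3 pairs, by -2.09 on the log2 scale (exact sign-flip p = 0.25, again the smallest possible). The levels of the other 12 lists overlapped between the groups, with exact permutation p from 0.143 to 0.971. Of these, pericyte (-0.55) and lymphocyte (-0.18) markers were lower and macrophage and monocyte markers (0.20) higher in 3 of 3 pairs, at the same sign-flip p of 0.25.

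No single gene passed the threshold between distended and control veins with edgeR's quasi-likelihood test. Of 10261 genes 135 had an unadjusted p under 0.05, fewer than chance alone would give. DESeq2 (75 genes at an unadjusted p under 0.05) and limma-voom (136) also called 0. The genes of lowest p that moved the same way in all 3 dogs were, on the lower side, IL1R2, a decoy receptor for interleukin 1 (log2 fold change -2.32 ± 0.57 SE), S100A8, a calcium-binding protein abundant in neutrophils (-1.29 ± 0.36), SERPINA1, the antitrypsin gene (-1.76 ± 0.48), TRIB1 (-1.29 ± 0.39) and BCL2A1, an inhibitor of apoptosis (-1.66 ± 0.50). On the higher side they were PPP1R3C, a glycogen-targeting phosphatase subunit (1.32 ± 0.44), PRG4, the gene of lubricin (3.52 ± 1.07), MAP3K6 (2.00 ± 0.71), TP53RK (1.38 ± 0.51) and C7H1orf53 (1.67 ± 0.63). The edgeR adjusted p was 1 for each of these 10 genes.

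Fitted with the dog as a block, edgeR called 12 genes, 3 higher and 9 lower, and 324 had an unadjusted p under 0.05. The lower genes included S100A9, the partner of S100A8 (blocked log2 fold change -2.45 ± 0.37 SE, adjusted p = 5.0e-07), CXCL8, a neutrophil chemoattractant (-1.98 ± 0.37, adjusted p = 3.5e-04), SERPINA1 (-2.08 ± 0.39, adjusted p = 4.2e-04) and CSF3, the granulocyte growth factor (-3.51 ± 0.67, adjusted p = 5.5e-04). CSF3 was lower in 2 of 3 pairs, stood at 104.0 CPM in the control vein of dog 2 and was at 0 CPM in the control and 5.79 CPM in the distended vein of dog 4. FFAR2, NAMPT, PLEK, SLA and GADD45A were the other lower genes, named here because the block called them, with SLA and GADD45A lower in 2 of 3 pairs. The higher genes were PRG4 (4.03 ± 0.85, adjusted p = 0.00368), CCL21, a lymphatic chemokine (3.81 ± 0.88, adjusted p = 0.0156), and LOC479668. PRG4 stood at 48.5 and 81.1 CPM in distended dogs 2 and 4 and at 1.73 CPM in distended dog 3, and CCL21 and LOC479668 stood at 0 CPM in the control veins of dogs 2 and 3. CCL21 was higher in 2 of 3 pairs, and LOC479668 had the opposite sign without the block (-2.43 ± 2.24). DESeq2 with the block called 1 gene, and the edgeR block called 49, 6 and 20 genes without dogs 2, 3 and 4.

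Of the 23 gene lists tested, the neutrophil list was lower in distended veins (camera, adjusted p = 0.00232). None of its 10 tested members passed the threshold over all genes and 3 were lower when adjusted over the list alone. S100A9 was at 26.0 ± 22.6 CPM (SD, n = 3) in distended and 135 ± 63.7 CPM (SD, n = 4) in control veins, S100A8 at 33.1 ± 13.5 and 86.0 ± 14.0 CPM, and S100A12 at 14.1 ± 13.5 and 44.7 ± 17.7 CPM. The median log2 fold change of the list was -1.28, or -0.64 with genes at 0 counts in a group set to their bound. With an estimated correlation the adjusted p was 0.860, and with fry it was 0.901, so the call rests on the preset correlation. Leaving out control 1, control 2, distended 2 or distended 4 gave 3 called lists and leaving out control 3 gave 2, each time with the neutrophil list among them at an adjusted p of at most 0.0360. Without the grafted library too few of its members passed the filter for a test.

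The block on the dog gave 5 called lists for distended against control, each at an adjusted p of 0.920 with an estimated correlation. The neutrophil list was lower (adjusted p = 0.00175), as was the list of inflammatory cytokines and adhesion (0.0439), whose members of lowest p without the block were CXCL8 (35.2 ± 19.2 CPM distended, 102 ± 69.4 CPM control), SOD2 (99.3 ± 21.0 and 176 ± 64.2), ICAM1 (241 ± 107 and 385 ± 131) and CSF3 (3.82 ± 1.82 and 30.8 ± 49.0). Fibroblast (0.00643), adipocyte (0.00175) and ribosomal protein (0.00643) lists were higher with the block. The direction of the first 2 depended on it, since their median log2 fold change was 0.44 and 1.77 with the block and -0.25 and -1.16 without, where camera gave the fibroblast list as higher and neither was called. The adipocyte marker level was higher in 1 of 3 pairs, and of the adipocyte members named below PNPLA2 (-0.45), PLIN4 (-0.064) and LPL (-0.031) had blocked log2 fold changes below 0 and ACACB (0.95) above. Without the block no member of the 4 lists added here passed the threshold, and none did when adjusted over the list alone. DCN, a matrix proteoglycan of fibroblasts, was at 1108 ± 52.0 CPM in distended and 2002 ± 2000.4 CPM in control veins, COL3A1 at 2657 ± 744 and 1941 ± 1056 CPM, ABCA8 at 19.7 ± 4.73 and 33.6 ± 21.8 CPM and MFAP5 at 107 ± 13.6 and 211 ± 232 CPM. PNPLA2, a triglyceride lipase, was at 159 ± 60.6 and 238 ± 82.6 CPM, PLIN4 at 56.4 ± 15.6 and 134 ± 151 CPM, LPL at 28.2 ± 19.9 and 50.4 ± 34.5 CPM and ACACB at 4.80 ± 4.20 and 10.0 ± 16.0 CPM. RPS3A, RPS24, RPS13 and RPL26 had log2 fold changes of 0.45 ± 0.31, 0.41 ± 0.32, 0.38 ± 0.32 and 0.40 ± 0.34.

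The grafted vein was compared with control veins to ask what differed 24 h after implantation. Because the graft had been distended too, this difference includes distension. All 10 tested members of the neutrophil list and 11 of 17 of the macrophage and monocyte list were higher in the graft, and 18 of the 19 tested smooth muscle genes were lower. The neutrophil list has 16 members, and without the grafted library fewer than 5 pass the filter, so most of the 10 were tested because the graft holds their counts. The filter asked for enough counts in a single library. Members of other lists can therefore also have been tested because the graft holds their counts. In all, 881 genes were higher and 897 lower of 10261 tested (edgeR, Benjamini-Hochberg adjusted p under the threshold). With total counts in place of TMM the split was 1305 and 715, with a median shift of all genes of 0.26 log2, with DESeq2 it was 509 and 910, and with each spot weighing the same it was 2958 and 34. The last setting averages log values of single spots, so its split can follow spot depth, which was highest in the graft.

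The largest increases included SMPDL3A, a phosphodiesterase related to acid sphingomyelinase, at 1682 CPM in the graft and 4.89 ± 2.02 CPM (SD, n = 4) in control veins (log2 fold change 8.28 ± 0.50 SE, adjusted p = 7.6e-09), and TFPI2, a serine protease inhibitor of the matrix, at 1597 and 8.50 ± 15.0 CPM (7.28 ± 1.38, adjusted p = 0.0177). SERPINB2, plasminogen activator inhibitor 2, stood at 501 CPM against 3 counts over the 4 controls, a ratio of 177 to 2511 by its 95% counting interval, and PROK2, a chemoattractant peptide of leukocytes, at 72.0 CPM against 1 count, a ratio of 39.5 to 8857. Several genes were at 0 counts in all 4 controls. OLR1, a receptor of oxidised lipoprotein, was at least 68.6-fold higher in the graft, SLPI, a leukocyte protease inhibitor, at least 50.6-fold, NRG1, an epidermal growth factor family ligand, at least 40.8-fold, and CA2, a carbonic anhydrase, at least 39.2-fold. BCL2L15 was at least 30.6-fold higher, RAB37 at least 28.6-fold, the neutrophil collagenase MMP8 at least 26.1-fold and CLEC7A, a receptor of fungal glucans, at least 24.9-fold.

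The largest decreases were mostly of genes at 0 counts in the graft. FAM180B was at least 49.4-fold lower than in control veins (58.7 ± 51.5 CPM), FN3K, a kinase that acts on glycated proteins, at least 48.8-fold (58.0 ± 18.7 CPM), AMIGO2, an adhesion molecule, at least 31.2-fold (37.1 ± 4.70 CPM), NTF3, the gene of neurotrophin 3, at least 29.0-fold and FAM180A at least 24.9-fold. SNORC was at least 19.7-fold lower, BTC, an epidermal growth factor family ligand, at least 19.2-fold, NPY2R, a receptor of neuropeptide Y, at least 18.7-fold, PNMT, the enzyme that makes adrenaline, at least 18.3-fold, LGI1 at least 17.9-fold and GPER1, an oestrogen receptor of the cell surface, at least 16.7-fold. PLXDC1 had 1 count in the graft against 97.8 ± 80.7 CPM in control veins, a ratio of 66.2 to 14666.

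Among muscle genes, the 18 called smooth muscle members were led by PLN, a regulator of the calcium pump, with a log2 fold change of -4.82 ± 0.75 (SE), SYNPO2 at -4.64 ± 0.65, MYL9, the regulatory myosin light chain, at -4.29 ± 0.72 and MYH11, the smooth muscle myosin heavy chain, at -4.14 ± 0.63. MYH11 fell from 4646 ± 1224 CPM (SD, n = 4) to 317 CPM. In the pericyte list NOTCH3 was the 1 lower member of 6 (-3.31 ± 0.59), and in the skeletal muscle list CKM, muscle creatine kinase (-4.78 ± 1.26), and CASQ1 (-3.49 ± 0.79) were the 2 lower of 8. Adjusted over the list alone, 19 smooth muscle, 3 pericyte and 3 skeletal muscle members were lower. The 3 lists were lower as sets (camera, adjusted p = 9.7e-16, 0.00506 and 0.00506), with an adjusted p of 0.131 for each with an estimated correlation.

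Part of the fibroblast, collagen and nerve lists was also lower. In the fibroblast list 8 of 21 members fell, with SERPINF1 at -3.70 ± 0.86, OGN at -3.46 ± 1.05, IGFBP6 at -3.45 ± 0.74 and the complement gene C7 at -3.23 ± 0.64, and 13 did not pass. In the list of collagen and elastic fibre 8 of 22 fell, with MFAP4 at -3.95 ± 0.60, COL14A1 at -3.45 ± 0.53, COL6A1 at -3.07 ± 0.79 and EFEMP2 at -2.56 ± 0.50. In the Schwann cell and nerve list 3 of 8 fell, among them SCN7A, with 1 count in the graft and a ratio of 4.51 to 1096, and CDH19 at -2.80 ± 0.76. Adjusted over the list alone, 8 fibroblast, 8 collagen and elastic fibre and 7 Schwann cell and nerve members were lower and 1 fibroblast member was higher. The lists were lower as sets (camera, adjusted p = 2.8e-04 for fibroblast, 4.6e-06 for collagen and elastic fibre and 6.5e-04 for Schwann cell and nerve). With an estimated correlation their adjusted p was 0.457, 0.131 and 0.131, and fry gave 0.175 for the fibroblast list.

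The neutrophil list was higher as a set (camera, adjusted p = 9.7e-11, and 0.131 with an estimated correlation), with MMP8, the gelatinase MMP9 (at least 20.4-fold), the activating receptor TREM1 (at least 18.0-fold) and the formyl peptide receptor FPR2, at 67.7 CPM against 2 counts in the controls, a ratio of 28.6 to 872. Of the macrophage and monocyte list 11 of 17 members rose and 1 fell (camera, adjusted p = 4.7e-05, and 0.192 with an estimated correlation). The scavenger receptor MARCO stood at 64.1 CPM against 2 counts in the controls (ratio 27.0 to 827), MS4A7 at a log2 fold change of 5.77 ± 0.72, the lysosomal protein CD68 at 4.63 ± 0.62 and AIF1 at 4.35 ± 0.50. In the list of phagocyte activation and lipid handling 7 of 16 rose and 1 fell, led by SPP1, the gene of osteopontin (5.39 ± 0.62, 885 CPM against 17.8 ± 5.73 CPM), the lysosomal protease CTSB (3.20 ± 0.40), the lipid droplet protein PLIN2 (2.58 ± 0.45) and the fatty acid carrier FABP5 (2.58 ± 0.74). That list had an adjusted p of 0.00545 with camera, 0.228 with an estimated correlation and 0.119 with the dog as a block. Adjusted over the list alone, 10 neutrophil members were higher, 11 macrophage and monocyte members higher and 2 lower, and 8 members of the phagocyte list higher and 1 lower.

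Some inflammatory, glycolytic and cell cycle genes were higher, and most members of the first 2 lists did not pass. In the list of inflammatory cytokines and adhesion 4 of 17 rose, namely CXCL8 (5582 CPM against 102 ± 69.4 CPM, log2 fold change 5.51 ± 0.69), IL11 (32.1 CPM against 1 count, ratio 17.3 to 3968), IL33 (3.96 ± 0.56) and SOD2, the mitochondrial superoxide dismutase (3.24 ± 0.41), and 1 fell. In the list of hypoxia and glycolysis 8 of 24 rose, with HK2, a hexokinase (3.77 ± 0.82), VEGFA, the angiogenic growth factor (2.40 ± 0.41), and SLC2A1, a glucose transporter (1.98 ± 0.53), while ADM, the gene of adrenomedullin, fell (-3.41 ± 1.02). In the cell cycle list 5 of 8 rose, with PCNA at 2.82 ± 0.42, the replication helicase subunits MCM2 at 3.34 ± 0.77 and MCM3 at 1.93 ± 0.63, and RRM2 at 36.8 CPM against 3 counts in the controls, a ratio of 12.6 to 188. The cell cycle list has 22 members, and MCM2 and MCM3 stood at 2.29 and 8.49 CPM in control veins against 43.1 and 36.8 CPM in the graft. Its count and its test as a set thus partly rest on members that pass the filter through the graft. The counts adjusted over the list alone were 4 higher and 1 lower for the inflammatory, 9 and 1 for the hypoxia and 6 and 0 for the cell cycle list. The lists were higher as sets (camera, adjusted p = 0.0165, 0.00866 and 0.00273). With an estimated correlation their adjusted p was 0.457, 0.192 and 0.131, and fry gave 0.102 for the inflammatory list.

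**Figure D2:**
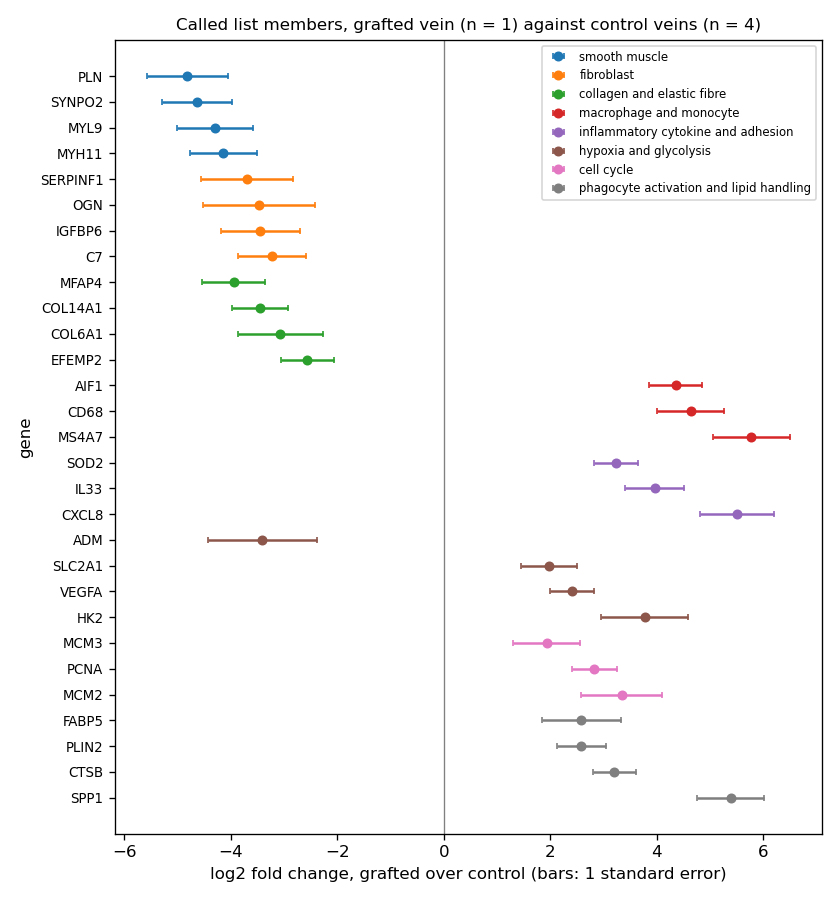
Log2 fold change of the grafted vein (n = 1) over control veins (n = 4) for up to 4 called members of 8 gene lists, coloured by list, with bars of 1 SE from edgeR on a linear axis. Members with 3 or fewer counts in the lower group are not drawn. Smooth muscle genes lie between -4.82 and -4.14, and CXCL8 at 5.51 and SPP1 at 5.39 lie on the higher side.

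In the fit with the dog as a block, in which the graft is set against the control vein of dog 1, 662 genes were higher and 941 lower, and 1268 genes were called in the same direction in both fits. The adipocyte list was lower with the block (adjusted p = 2.0e-09, and 0.311 with an estimated correlation) and was not called without it (0.1005). Its PLIN4 had a blocked log2 fold change of -6.42 and LPL one of -2.57. ADIPOQ and LEP stood at 0 counts in the graft, at least 3.36-fold and 2.08-fold below the control mean. Control 1 held 17.2 adipocyte marker UMIs per 10000 and the other controls at most 4.23. The ribosomal protein list (0.0358, lower as a set, and 0.848 with an estimated correlation) and the unfolded protein list (0.0475, higher, and 0.311 with an estimated correlation) were also called only with the block. The called members without the block were RPL22L1 (2.31 ± 0.51) and RPS12 (1.29 ± 0.42) in the former, both against the direction of the set. In the latter 4 of 16 were higher and 1 lower, and those of largest change were the chaperone HSPA5 (1.40 ± 0.39), CEBPB (1.63 ± 0.46) and SDF2L1 (1.67 ± 0.43) on the higher side and VLDLR (-3.87 ± 0.82) on the lower. Adjusted over the list alone, 0 adipocyte members, 1 ribosomal protein member (higher) and 5 unfolded protein members (4 higher) were called.

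The lists of endothelial, immediate early, heat shock, YAP and TEAD target, matrix remodelling, coagulation, nuclear oxidative phosphorylation and interferon response genes were not called in the graft (camera, adjusted p from 0.111 to 0.808). The interferon list had a median log2 fold change of -0.094 where camera gave the opposite sign. The block ended the calls of SNORC (adjusted p = 0.284), RPS12 (0.123), FABP5 (0.0896) and MCM2 (0.0543), and DESeq2 those of MMP9, SERPINB2, MCM3, TREM1, TFPI2, SLC2A1, CLEC7A and FABP5 (adjusted p from 0.0546 to 0.568). Leaving out 1 library ended those of MCM3 (without control 1, 3 or 4 or distended 3), SNORC (control 2 or 4, distended 2 or 4), FABP5 (control 2 or 4, distended 2), RPS12 (control 2, 3 or 4, distended 3 or 4), ADM (control 4, distended 3 or 4), BTC (control 3 or 4), OGN (control 1) and TFPI2 (control 3), with adjusted p from 0.0502 to 0.131. Limma-voom ended the calls of BTC and SNORC, total counts those of OGN and ADM, upper quartile scaling that of RPS12 and spots of 500 or more UMIs that of OGN. Thinning to the smallest library ended those of NTF3, SERPINF1, OGN, CASQ1, ADM, SDF2L1 and RPS12, equal weight for each spot ended 28 (adjusted p from 0.0569 to 0.413), and the edgeR function for thinning ended 33 (0.0560 to 0.636). DESeq2 with the dog as a block ended 15 (0.0519 to 0.771), among them SPP1 (0.213), PLIN2 (0.107), CDH19 (0.309), SCN7A (0.172), VLDLR (0.152) and RPL22L1 (0.198).

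The grafted vein was also set against the distended veins, which come from other dogs, so that dog and condition are not separated. Both had been distended. The difference resembled that against control veins in size, with 849 genes higher and 844 lower (edgeR). The largest increases were of genes at 0 counts in the 3 distended veins. SERPINB2 was at least 373-fold higher, C17H1orf162 at least 175-fold, MCEMP1, a membrane protein of mast cells and monocytes, at least 127-fold, the interleukin 18 receptor subunit IL18RAP at least 79.0-fold and the interleukin 22 binding protein IL22RA2 at least 56.0-fold. The largest decreases were of FAM180B (at least 52.7-fold), FN3K (43.2-fold), AMIGO2 (39.1-fold), NTF3 (38.2-fold) and FAM180A (26.4-fold), all at 0 counts in the graft. With each spot weighing the same the split was 3642 higher and 5 lower, and with total counts it was 1177 and 685. The first of these splits can follow spot depth. DESeq2 ended the calls of SERPINB2 (adjusted p = 0.223), IL18RAP (0.115) and IL22RA2 (0.432), and equal weight for each spot those of the 5 lower genes (0.139 to 0.236). The edgeR function for thinning ended 7 of the 10 calls (0.0591 to 0.170), and FAM180A had no test under it.

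To compare the response to distension with that of the graft, fold changes within dogs were correlated across the 10261 genes, which are not independent replicates. The graft over the control of dog 1 and the mean of distended over control of dogs 2, 3 and 4, which share no library, had a Pearson r of -0.119, a Spearman rho of -0.079 and the same sign in 47.8% of genes. In the fits that share the 4 controls r was -0.0075, where 20 simulations of unchanged groups gave 0.346 ± 0.0186 (SD). The covariance was -0.0069 against 0.165 simulated, a difference of -0.171.

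Spots fell into 6 regions. Region 5, the muscle region, was led by TNC, SPEG, ATP2A2, MTCL1 and NTF3 and had the highest smooth muscle level over all libraries (673 UMIs per 10000). That level was 692 in its control, 771 in its distended and 78.3 in its 152 grafted spots, where region 6 stood higher at 172. Region 1, the fibroblast region, was led by PCOLCE2, PI3, SCARA5, C1S and F3, with 487 fibroblast UMIs per 10000 over all libraries, 531 in its control, 515 in its distended and 87.7 in its 104 grafted spots. Grafted spots of region 6 stood higher, at 112. Region 3 was led by SELE, FABP4, ACKR1, LOC479668 and SOX17, and had the highest endothelial (83.4) and adipocyte (55.5) levels over all libraries, with 70 of its 156 spots in control 1 and 44 in the graft. Its adipocyte level was 91.0 in control, 44.5 in distended and 3.16 in grafted spots, and its endothelial level 79.4, 111 and 67.1. Region 4 was led by LOC119877775, TNRC6A, LOC119877774, GEMIN5 and RBM25. Region 2 was led by LOC100855558, LOC100855540, LOC480784, S100A12 and SERPINA1 and had 138 neutrophil UMIs per 10000 over all libraries, with 285 of its 455 spots in the graft. That level was 31.7 in its control, 19.8 in its distended and 204 in its grafted spots. Grafted spots of the other regions stood at 31.2 to 96.8. The first 3 leading genes of region 2 lie beside HBQ1, HBM and HBE1, and their identity is not known here. They are the 3 unnamed genes left out in an alternative below. Region 6, led by LOC478702, ACTA1, PNCK, COL1A1 and MFAP4, had 231 of its 241 spots in the graft, and its leading genes rest on 1 section.

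Distended veins had 32.3% to 40.9% of their spots in the fibroblast region and 43.2% to 60.5% in the muscle region, against 25.3% to 37.1% and 32.6% to 50.9% in control veins. The shares of the graft are not compared, because genes that lead these regions differed there.

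Within regions, distended and control veins were compared to ask whether a response was hidden in the whole section. No gene passed the threshold with edgeR in the fibroblast region (0 of 4657 genes, 72 at an unadjusted p under 0.05), region 4 (0 of 835, 10) or the muscle region (0 of 9038, 109). With the dog as a block 5, 2 and 4 genes were called. The effect of distension did not differ between the muscle and the fibroblast region for any of 4058 genes past the threshold (60 at an unadjusted p under 0.05). Each of these counts at an unadjusted p under 0.05 is smaller than chance alone would give. No other tool was run within regions.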

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

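The tests of the neutrophil pattern, of muscle share and thinning in the graft, and of another animal and other DLA genes for DLA88 were chosen only after the result was seen. Each value of the control veins was also compared with the other 3, and in 18 of 122 such comparisons 1 control lay further from the others than Dixon's 95% limit allows, where chance alone does so in about 1 of 20 for normally distributed values. In 7 of the 18 the other controls stood at 0, so that any count at all passes the limit.

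Neutrophil markers were lower in the 3 distended veins than in the 4 control veins, by -1.94 on the log2 scale. The difference was -1.30 without the shallow library of distended dog 4 and -1.76 without the highest control, which argues against either library as the whole cause. Less blood left in the distended sections stays a candidate explanation. The platelet list differed by 0.445 (exact permutation p = 0.543) with overlapping libraries and decides nothing. The red cell list differed by -0.070 (exact permutation p = 0.971). Only 5 of its 9 members were in the files and 1 was tested, so it decides nothing either. Unnamed genes beside HBQ1, HBM and HBE1 lie outside that list, and their summed level was not compared between the groups. Distension itself, named by the design, stays open and untested against less blood. Pressure and the saline solution with papaverine and bivalirudin came together in the distended veins and cannot be told apart here. For the lists as a whole chance cannot be excluded, since 34 of the 35 splits of the 7 libraries called as many lists as the real one (1), and the highest other called 10.

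The grafted vein differed from control veins in 1778 genes. The spread between single libraries is argued against as the cause, since 1 control set alone against the others called at most 58 genes, and a lower share of muscle that lifts all other markers alike is argued against by fibroblast markers, which stood at 0.315 of the control mean and below each control. Greater depth is argued against by 756 calls after sampling each library down to the smallest, but that tool replaced the edgeR function for thinning, whose 333 calls fell between the bounds of the test, and over 10 further draws of each tool sampling gave 732 to 810 calls and the edgeR function 368 to 464, 3 of them past the bound of 444.5, so the verdict depends on the tool and this test is weaker than the others. Entry of myeloid cells, death or loss of muscle, the distension at harvest that the graft also had, the place of the section and the single dog stay open, and the state of the vein 24 h after bypass, which the design names, was not tested apart from them. The controls set alone were each shallower than the graft. That test covers the spread of control libraries only, since a single graft cannot show how grafts vary.

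DLA88, a class I histocompatibility gene that varies between dogs, was singled out after its values were seen, at 502 CPM in the control and 6.33 CPM in the grafted vein of dog 1, while the 2 libraries of dogs 2, 3 and 4 lay at 6.50 and 2.20, 10.3 and 3.46, and 113 and 127 CPM. A different mix of regions is argued against, since the lowest region of control 1 stood 27.3-fold above the highest region of the graft (95% exact counting interval 7.47 to 227, on 2 counts in the graft), and so is counting under other genes named DLA, which gained -8.59% of the lost CPM. Another animal under 1 of the labels stays open, since 22.7% of 22 other dog-specific genes were over 4-fold apart in dog 1 (95% exact interval 7.82% to 45.4%) against 8.18% of the genes nearest in mean expression. An earlier form of that test had DLA88 among 23 genes and, as background, all 8504 genes in the range of their means. It gave 26.1% against 8.33%, with an interval (10.2% to 48.4%) above the background. Neither form can tell another animal from a change in the graft. The genes were picked for differing between dogs, while each background was chosen by mean expression alone. A change of DLA88 in the graft, which the design allows, was not tested apart from another animal. The fit with the dog as a block takes the label of dog 1 as given.

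For distended against control veins, chance cannot be excluded for the count of genes at an unadjusted p under 0.05. The real split had 135 genes at an unadjusted p under 0.05, a number that 35 of 35 splits reached, with 1141 in the highest other. It called 0 genes with edgeR, a count that all 35 of 35 splits reach by construction and that tests nothing, and the highest other split called 29. The 2 splits with the most calls, picked after they were seen, set control 1, control 4 and distended 2 (29 genes) or control 2, control 3 and distended 3 (24 genes) against the rest. They may point to a structure of the samples other than distension, which was not tested. Within regions the real counts of 0 are likewise reached by 35 of 35 splits whatever the data, and the highest other split called 25 genes in the fibroblast region, 112 in the muscle region and 9 for the difference between them. With the dog as a block the real arrangement called 12 genes and the highest of the others 21, and 3 of 4 arrangements called as many, which are too few splits for a share under 0.05.

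Control 1 stood above the other controls for adipocyte markers (17.2 UMIs per 10000, others 2.27 to 4.23) and for platelet markers (0.869, others 0.065 to 0.181). Its PLIN4 was at 360.6 CPM (others 51.6 to 62.0), ABCA8 at 66.0 CPM (18.2 to 25.8), COL6A1 at 934 CPM (277 to 372), ADIPOQ at 15.9 CPM, RRM2 at 1.65 CPM and PROK2 at 0.550 CPM, the last 3 at 0 in the other controls. Control 2 stood above the others for CSF3 (104.0 CPM, others 0 to 11.5), TFPI2 (30.9 CPM, others 0 to 2.58) and IL18RAP (3.25 CPM, others 0 to 0.550). Control 2 was also the 1 control with counts of SERPINB2 (4.88 CPM), IL22RA2 (4.88 CPM), MARCO (3.25 CPM) and IL11 (1.63 CPM). Control 4 stood above the others for FAM180B (135 CPM, others 22.8 to 41.3) and OGN (712 CPM, others 180 to 265). PRG4 stood at 0 CPM in control 3 and at 3.25 to 3.85 CPM in the others. Values under 5 CPM in these libraries rest on a handful of counts.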

How the results depend on the processing

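Of the alternatives below, DESeq2 with the dog as a block, the block without 1 dog, thinning by sampling without replacement, which replaced the edgeR function run first, 10 further draws of each, the control of dog 1 left out together with the distended vein of dog 4, the 3 unnamed genes left out and the agreement of a single dog's pair were chosen after the data were seen. Counts, lists and other summary results stayed within 1.5 times or kept their side of the threshold in 133 cases, moved in 45 and changed sign in 1. Values of single genes, lists and levels kept their direction and their side of the threshold in 2890 cases, gained a call in 57, lost one in 166 and changed sign in 94. A gene with the same direction but no adjusted p under an alternative counts among the 2890 and not among the lost calls. Where no cause is named below, the cause was not tested. At the depth and number of these libraries the simulated test recovered 2.5% of genes changed 2-fold between distended and control veins, so changes of that size would mostly be missed. Without the grafted library fewer than 5 members of the neutrophil list passed the filter, so that list had no test in the 7 other libraries. A minimum of 50 spots left too few libraries for region 4.

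Distended against control called 0 genes with DESeq2, limma-voom, upper quartile and total count scaling, the stricter filter, spots of 500 or more UMIs, either thinning, equal weight for each spot, the 7 libraries alone, male dogs alone and the 3 unnamed genes left out. With no filter it called 5. Leaving out each library in turn gave 0 to 1. With the dog as a block it called 12 genes by edgeR and 1 by DESeq2, and by edgeR 49 without dog 2, 6 without dog 3 and 20 without dog 4.

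Grafted against control called 1419 genes by DESeq2, 2345 by limma-voom and 1445 to 1865 with each library left out. It gave 583 by DESeq2 with the dog as a block, 756 after sampling to the smallest library, where 4956 genes passed the filter, and 333 with the edgeR function for thinning (732 to 810 and 368 to 464 over 10 further draws of each). With each spot weighing the same, 2992 genes were called, 2958 of them higher. That setting can follow spot depth. Grafted against distended gave 754, 337 and 3647 under the last 3 settings. Leaving out each library gave 1260 to 1855 for that comparison.

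Some log2 fold changes that were not called changed sign. For distended against control with equal weight for each spot, RPS3A was at -0.17, RPS24 at -0.14, RPS13 at -0.11 and RPL26 at -0.10. These are differences of mean log2 values over spots, not fold changes of summed counts. With the dog as a block DCN was at 0.26, MFAP5 at 0.44 and ACACB at 0.95, and by DESeq2 with the block at 0.25, 0.42 and 1.26. With the block and without dog 2, MFAP5 was at 0.083, PLIN4 at 0.23 and ACACB at 5.49. Without dog 3, DCN was at 0.12 and MFAP5 at 0.17. Without dog 4, DCN was at 0.69, MFAP5 at 1.04, PLIN4 at 0.031, LPL at 0.47 and ACACB at 0.93. Without the control of dog 1 and the distended vein of dog 4, DCN was at 0.12, MFAP5 at 0.30, PLIN4 at 0.083 and LPL at 0.22. With each library left out in turn, DCN ranged from -1.13 to 0.11 and MFAP5 from -1.29 to 0.22, both highest without control 1. For grafted against control, LPL was at 1.35 with the edgeR function for thinning.

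For the gene lists, the estimated correlation left 0 calls for distended and 0 for grafted against control, and fry left 0 and 10. The block gave 5 lists for distended and 14 for grafted against control. Leaving out each library gave 1 to 3 lists for distended against control and 12 to 13 for grafted against control. Directions that changed with the block, with the adjusted p there, were smooth muscle 0.342, endothelial 0.826, macrophage and monocyte 0.770, adipocyte 0.00175, coagulation 0.928 and phagocyte activation 0.922 for distended, and immediate early 0.821 and interferon 0.358 for grafted against control. By fry the fibroblast list had the opposite sign, at 0.993. For distended against control with each library left out in turn, the sign was not stable for some lists. Their adjusted p ranged from 0.156 to 0.968 for smooth muscle and endothelial, 0.0150 to 0.968 for fibroblast, 0.0132 to 0.913 for macrophage and monocyte, 0.123 to 0.968 for adipocyte, 0.244 to 0.991 for skeletal muscle and 0.156 to 0.984 for Schwann cell and nerve. The ranges were 0.0123 to 0.566 for immediate early, 2.8e-04 to 0.797 for inflammatory cytokines, 0.244 to 0.999 for collagen, 0.414 to 0.941 for coagulation, 0.382 to 0.985 for hypoxia, 0.0588 to 0.965 for interferon and 1.9e-06 to 0.803 for ribosomal proteins. For grafted against control they were 0.314 to 0.934 for immediate early and 0.756 to 0.934 for oxidative phosphorylation.

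Among the marker levels of distended against control, 1 list had an exact p under 0.05. That count was 0 with each library left out, 0 with within-dog differences (dog as a block) and 0 with the median over spots, where the first 2 designs cannot reach 0.05. With the dog as a block the log2 difference turned to -0.013 for smooth muscle, 0.11 for endothelial, 0.20 for macrophage and monocyte, 0.10 for adipocyte, -0.12 for skeletal muscle and 0.052 for red cell markers. With the median over spots it was -1.17 for skeletal muscle. With each library left out it ranged from -0.013 to 0.32 for smooth muscle, -0.30 to 0.46 for fibroblast, -0.30 to 0.11 for endothelial, -0.40 to 0.20 for macrophage and monocyte and -0.052 to 0.92 for mast cell. The ranges were -0.85 to 0.10 for adipocyte, -0.20 to 0.19 for skeletal muscle, -0.27 to 0.19 for Schwann cell, -0.50 to 0.37 for red cell and -0.11 to 0.97 for platelet markers. The difference in ribosomal protein share ranged from -0.494 percentage points without distended 4 to 1.91.

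Within regions the block called 5 genes in the fibroblast region, 2 in region 4 and 4 in the muscle region, and leaving out each library called 0 to 1 in each region and for the difference between regions. Resolution 0.3 gave 4 regions. Resolution 0.8 and scaling over all spots gave 6, but with the latter 1 region held 961 spots of the graft, 2 of distended and 0 of control veins. With a pseudocount of 20 CPM and sections of 5 or more spots, chosen after the data were seen, regions 1 to 6 shared 4, 4, 2, 3, 2 and 0 of their 5 leading genes with the first ranking. The within-dog correlation of grafted and distended fold changes was -0.219 over genes of 50 or more CPM, and -0.113, -0.057 and -0.050 with the pair of dog 2, 3 or 4 alone.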

Other observations

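Several process lists held called genes in the graft without a call for the list. In the list of matrix remodelling 5 of 24 members were higher and 3 lower (edgeR) and camera gave an adjusted p of 0.189. In the list of YAP and TEAD targets 1 of 16 was higher and 4 lower, in the endothelial list 1 of 16 higher and 2 lower, and in the coagulation list 2 of 12 higher and 1 lower. The heat shock list had 2 of 16 members higher and 0 lower, and the list of nuclear oxidative phosphorylation 2 of 43 higher and 1 lower. Members of these lists went both ways, and their median log2 fold changes lay between -0.34 and 0.43.

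Beside DLA88, 3 more genes with large differences between libraries are given here, chosen after their values were seen, of which the first differed between dogs and the other 2 mainly between the 2 libraries of dog 1. LOC102156855 stood at 29.2 CPM in the control and 40.6 CPM in the distended vein of dog 4 and at 0 CPM in the other 6 libraries. LOC608379 stood at 189 CPM in the control vein of dog 1, at 0.40 CPM in the grafted vein of dog 1 and at most at 3.65 CPM in the other libraries. CD24, a surface glycoprotein, stood at 12.1 CPM in the control and 727 CPM in the grafted vein of dog 1, and at 3.65 to 39.0 CPM elsewhere. Between the same 2 libraries neutrophil markers were 42.1-fold higher in the graft. A large difference within dog 1 can thus be a change in the graft, which was not tested apart from another animal.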
